A study of Mus musculus with 7 samples.

How the data were processed

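RNA was sequenced from supporting cells of mouse cochleae at postnatal day 1, cultured for 48 h with DMSO, 10 µM GSK-343 or 200 nM TSA and sorted for GFP, per the labels. The 7 libraries (2, 3 and 2) were made with a kit for small RNA inputs. The labels do not say whether replicates are separate cultures or animals, so p-values measure only the spread between these samples.

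Reads were aligned with STAR and quantified per gene with RSEM on mm10, and DESeq2 was used for differential expression, per the submitters' processing notes. The expected counts and the TPM values deposited by the authors are RSEM's estimates per gene, per the file headers. An expected count shares ambiguous reads between genes and is not scaled between libraries; the deposited TPM values divide by effective length and are scaled to a fixed sum per library. Each table holds 48709 genes. Of these, 48349 matched GENCODE M21 after the version suffix was dropped (41341 with the same version), 360 did not, and 63 symbols belong to more than 1 gene; the release the authors used is not stated. Lengths minus effective lengths were read from the deposited tables to see how each library was quantified. Non-whole values made up 45.8% to 50.8% of the counts above 0 in DMSO and 11.0% to 13.0% in the treated libraries.

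Expected counts were rounded for edgeR 4.0.16 in R 4.3.3. Genes passing its filterByExpr function (14907) were tested in 1 model of all 7 libraries with 4 residual degrees of freedom. TMM factors were 0.754 and 0.76 for DMSO, 1.04, 1.08 and 1.02 for GSK-343, and 1.32 and 1.16 for TSA. The biological coefficient of variation was 0.43. Quasi-likelihood F tests compared TSA with DMSO, GSK-343 with DMSO and TSA with GSK-343, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM are TMM-normalised. For a gene with no count in a group, a fold is a lower bound against a floor of 3 counts per library, converted to TMM-normalised CPM. Before TMM scaling, 3 counts correspond to 0.502 to 1.10 CPM. Such bounds cover counting error only. The genes with an unadjusted p under 0.05 numbered 6081, 7240 and 4163 in these 3 comparisons.

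Gene groups were 48 lists of marker, pathway and complex genes, of which those with at least 5 tested members were tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and the rotation test fry) and adjusted over the lists. Members were also adjusted over their list alone. Lists, comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined, except the alternatives named below as added later and the tests of the many genes that differ from DMSO. The rule takes, per comparison, the 8 rising and 8 falling genes with the largest fold among those past the threshold with a mean log2 CPM of at least 3, TPM values that do not overlap and a named symbol, outside the mitochondrial genome; up to 4 members of each list described, by smallest adjusted p; and 11 fixed genes. Gapdh, and members named because they moved the same way in several comparisons, were chosen after their values were seen.

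The pipeline was tested on simulated data with 200 changed genes. It recovered 4.48%, 34.3% and 78.8% of genes changed 2-, 4- and 8-fold for TSA against DMSO, 4.48%, 46.3% and 75.8% for GSK-343 against DMSO, and 4.48%, 49.3% and 75.8% for TSA against GSK-343, with 5, 2 and 8 false calls. Replicates were checked for duplicates: the chi-square per degree of freedom between replicates was 15.0 to 44.2 and the correlation of log2 CPM 0.892 to 0.947.

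Alternatives were DESeq2 size factors, total count scaling, no low-count filter, a filter of 50 counts in 2 libraries, only the 2 groups compared, libraries thinned to the smallest, the replicate number as a block, each library left out in turn, the Wald test of DESeq2 1.42.0, limma on log2 TPM (19336 genes), a threshold of 0.01, and a 2-fold minimum. The filter was run again with each library left out. Without 1 DMSO or TSA library, 16383 to 17902 genes were tested. Removal of a spline trend on GC content and transcript length per library, and a test of protein-coding nuclear genes alone, were added after the data were seen. Overlap between the changes against DMSO was set against independent lists and against 20 simulations of unchanged groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Groups of 2 and 3 libraries are too small for permutation tests. Reads themselves were not analysed here.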

Results

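RNA sequencing was used to ask how 48 h of exposure to inhibitors of histone-modifying enzymes changes the transcriptome of cochlear supporting cells, the non-sensory cells that surround the hair cells of the inner ear. Per the labels, cochleae of mice at postnatal day 1 were cultured with DMSO, with trichostatin A (TSA, an inhibitor of histone deacetylases) at 200 nM, or with GSK-343 at 10 µM. GSK-343 inhibits EZH2, the methyltransferase of Polycomb repressive complex 2. GFP-positive supporting cells were then sorted by flow cytometry, and their RNA was made into libraries. There were 7 libraries: 2 from DMSO, 3 from GSK-343 and 2 from TSA. The total expected count was 5974230 and 5124247 in the DMSO libraries, 3398893, 3818798 and 4248336 in the GSK-343 libraries, and 2724381 and 2963228 in the TSA libraries. Below, expression is in TMM-normalised CPM, as mean ± SD with n = 2 for DMSO, n = 3 for GSK-343 and n = 2 for TSA. Fold changes of single genes are log2 values ± SE, with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test. That test gives no SE, so the SE was derived as the absolute log2 fold change over the square root of F.

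The DMSO libraries differed from the treated libraries in more than their treatment. In the deposited gene tables, the length of a gene exceeded its effective length by a median of 49 bases in both DMSO libraries and by 208.21 to 212.69 bases in the 5 treated libraries, so the reads of the groups were quantified in different layouts. Nuclear protein-coding genes held 62.5% and 63.4% of the counts in DMSO and 78.2% to 93.4% in the treated libraries. The mitochondrial ribosomal RNA mt-Rnr1 held 7.80% and 8.37% of the counts in DMSO and 0.0195% to 0.0965% in the treated libraries, and long intergenic RNAs held 3.15% and 4.16% against 0.35% to 0.541%. Counts above 0 were found for 25166 and 28754 genes in DMSO and for 15916 to 19251 genes in the treated libraries. Gapdh, a glycolytic enzyme often used as a reference gene, stood at 56.6 and 82.4 CPM in DMSO, at 673, 1123 and 796 CPM with GSK-343, and at 417 and 316 CPM with TSA. The TSA and GSK-343 libraries share a layout, so their direct comparison is given first. Every comparison with DMSO is also a comparison between layouts.

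**Figure D1:**
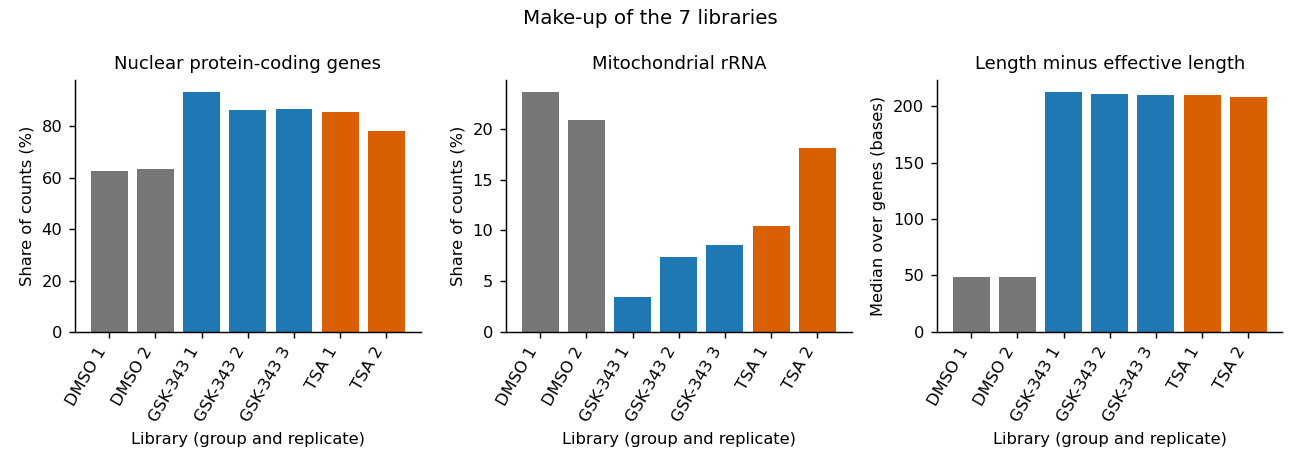
Share of counts in nuclear protein-coding genes (left, %), share in mitochondrial ribosomal RNA (middle, %) and median difference between gene length and effective length (right, bases) for each of the 7 libraries, 1 bar per library, coloured by group (grey DMSO, blue GSK-343, orange TSA). Both DMSO libraries sit at 49 bases in the right panel and all 5 treated libraries between 208.21 and 212.69.

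The first comparison asks whether the responses to the deacetylase inhibitor and to the EZH2 inhibitor differ. Genes of neurons were higher with TSA than with GSK-343. Stmn2, a tubulin-binding protein of growing neurites, stood at 103 ± 6.35 CPM with TSA and at 2.33 ± 0.723 CPM with GSK-343 (log2 fold change 5.45 ± 0.46, adjusted p = 5.65e-05). Snhg11, a long non-coding RNA enriched in neurons, rose by 4.72 ± 0.69, Map2, a microtubule-associated protein of dendrites, by 2.83 ± 0.43, and Scg5, a chaperone of secretory granules, by 2.18 ± 0.35. Of the 40 neuronal genes tested, 13 rose and 1 fell, or 16 and 1 adjusted over the list alone. Their median log2 fold change was 1.72, and they ranked above the other genes in a competitive gene set test (camera, adjusted p = 5.96e-08; adjusted p = 0.28 with an estimated correlation). Per library, the mean log2 CPM of these genes was 4.16 and 3.72 with TSA, 2.15, 2.14 and 2.53 with GSK-343, and 2.27 and 2.57 in DMSO. Of the 16 spiral ganglion neuron markers tested, 4 of which are also in the neuronal list, 4 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.027, and 0.458 with an estimated correlation). Snap25, a protein of synaptic vesicle release, rose by 2.89 ± 0.52 (adjusted p = 0.0052) and the neurofilament gene Nefl by 2.38 ± 0.67 (adjusted p = 0.0362). Without TSA replicate 1 the spiral ganglion list had an adjusted p of 0.113 and Nefl 0.426, and Nefl also missed the threshold without TSA replicate 2, GSK-343 replicate 1 or GSK-343 replicate 2 (0.0686, 0.0526 and 0.092).

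Supporting cell genes were lower with TSA than with GSK-343. Of 46 tested, 15 fell and 2 rose, or 18 and 2 adjusted over the list alone, with a median log2 fold change of −0.69 (camera adjusted p = 1.38e-05; adjusted p = 0.458 with an estimated correlation). Hey1, a transcriptional repressor downstream of Notch receptors, stood at 158 ± 48.1 CPM with TSA and 691 ± 68.2 CPM with GSK-343 (log2 fold change −2.13 ± 0.33, adjusted p = 0.00268). Emid1, an extracellular matrix protein, changed by −2.84 ± 0.44 and the calcium-binding protein gene S100a1 by −2.30 ± 0.38, from 6141 ± 2299 to 1249 ± 15.9 CPM. S100a1 stood lower still in DMSO (645 and 456 CPM). The list as a whole did not: its mean log2 CPM was 7.66 and 7.73 in DMSO, 7.18 to 7.33 with GSK-343, and 6.79 and 6.29 with TSA. Lrrn1, a leucine-rich repeat membrane protein, went the other way, with a log2 fold change of 2.48 ± 0.36 (adjusted p = 0.00195). Of 30 Notch pathway genes tested, 8 fell and 1 rose, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.027, and 0.505 with an estimated correlation), and of 10 Notch effectors tested, 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (0.0303 and 0.505). These lists share 7 and 5 genes with the supporting cell list. Hes5, a Notch target and repressor of hair cell fate, stood at 254 ± 12 CPM with TSA and 656 ± 108 CPM with GSK-343 (log2 fold change −1.37 ± 0.30, adjusted p = 0.0136). In DMSO Hes5 stood at 359 and 300 CPM, nearer to TSA. Dtx1, a ubiquitin ligase that acts on Notch, rose by 3.14 ± 0.79 (adjusted p = 0.0248). Among 12 markers of the medial cells next to the organ of Corti, 6 fell and 0 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0377, and 0.458 with an estimated correlation). Fkbp9, a folding enzyme of the endoplasmic reticulum, fell by 1.38 on the log2 scale (SE 0.29). When a trend on GC content and transcript length was removed per library, the supporting cell list kept an adjusted p of 7.13e-06, whereas Hes5 had a log2 fold change of −0.53 with an adjusted p of 0.336. The Notch lists then had adjusted p of 0.142 and 0.314. Without TSA replicate 2 the calls of Hes5, Dtx1 and Fkbp9 were lost (adjusted p = 0.121, 0.226 and 0.0716), and the Notch pathway list was at 0.0503. Dtx1 was lost also without TSA replicate 1 or GSK-343 replicate 3 (0.0852 and 0.0745). The medial list was lost without DMSO replicate 1, DMSO replicate 2 or GSK-343 replicate 1 (0.0846, 0.123 and 0.105).

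Genes of epithelial junctions, of sterol and fatty acid synthesis, of the ATF4 stress response and of the ribosome were also lower with TSA than with GSK-343. Of 24 epithelial genes tested, 8 fell and 0 rose (10 and 0 adjusted over the list alone; median −0.96; camera adjusted p = 1.62e-04, and 0.458 with an estimated correlation). The tight junction gene Cldn7 stood at 82 ± 4.41 CPM with TSA and 586 ± 156 CPM with GSK-343, a log2 fold change of −2.84 ± 0.36. Of 25 cholesterol synthesis genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.00221, and 0.505 with an estimated correlation). Srebf2, the transcription factor that drives this pathway, fell by 1.65 on the log2 scale (SE 0.34). Of 16 fatty acid synthesis genes, 4 fell and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0414, and 0.586 with an estimated correlation), among them the fatty acid synthase Fasn with −2.05 ± 0.40. Of 21 ATF4 response genes, 5 fell and 0 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0303, and 0.505 with an estimated correlation); Shmt2, a mitochondrial enzyme of serine metabolism, changed by −2.53 ± 0.40. Of 79 ribosomal protein genes, 23 fell and 0 rose (38 and 0 adjusted over the list alone; median −0.86; camera adjusted p = 1.79e-12, and 0.505 with an estimated correlation). Rpl36 fell by 3.02 on the log2 scale (SE 0.37) and Rps15 by 2.20 (SE 0.37). The ribosomal list had a mean log2 CPM of 6.15 and 6.53 with TSA, 6.49 and 6.41 in DMSO, and 6.86 to 7.46 with GSK-343. In the same order, the cholesterol list had 4.54 and 4.67, 4.76 and 4.66, and 5.07 to 5.83. The epithelial list had 5.69 and 5.30, 5.46 and 5.50, and 6.14 to 6.53. For these 3 lists TSA thus lay near DMSO and GSK-343 above it, across the difference in layout. Of 12 histone acetylation genes, 1 fell and 0 rose, and the same numbers held adjusted over the list alone (camera adjusted p = 0.0122, and 0.458 with an estimated correlation). Log2 fold changes followed GC content across the genes in this comparison (Spearman −0.368 over 14870 genes, which are not independent replicates). With the trend on GC content and length removed, the ribosomal list had a camera adjusted p of 3.3e-05, the epithelial list 0.0176, the cholesterol list 0.00157 and the ATF4 list 0.182. With protein-coding nuclear genes alone, the fatty acid list narrowly lost its call (0.05005). Without TSA replicate 2, Srebf2 and Fasn had adjusted p of 0.132 and 0.0826; the fatty acid list had 0.184 without GSK-343 replicate 3, 0.079 without TSA replicate 1 and 0.0561 with total count scaling.

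Hair cell genes did not separate the compounds, and the 2 TSA libraries differed from each other. Of the 60 hair cell function genes tested, 5 were higher and 2 lower with TSA, also adjusted over the list alone (median 0.27; camera adjusted p = 0.4), and of the 18 hair cell regulators tested, 1 was higher and 0 lower, also adjusted over the list alone (median −0.03, but mean 0.12, and a median of 0.05 with DESeq2's size factors and 0.29 with total count scaling; camera direction down, adjusted p = 0.791). The mean log2 CPM of the function list was 5.49 and 3.41 in the TSA libraries. Without TSA replicate 2 the function list was higher with TSA (median 1.14), and without TSA replicate 1 it was lower (median −1.24), as was the regulator list (median −1.42). With all libraries and an estimated correlation, the function list had a camera adjusted p of 0.91. The camera direction of the function list was also down without GSK-343 replicate 2 (adjusted p = 0.965). The regulator list turned higher with TSA without TSA replicate 2 (median 0.58) and without GSK-343 replicate 3 (adjusted p = 0.673), where the function list was higher too (adjusted p = 0.0448). Gpsm2, a polarity protein of the hair bundle, was 172 ± 14.9 CPM with TSA against 60.4 ± 4.65 CPM with GSK-343, a log2 fold change of 1.51 ± 0.32 (adjusted p = 0.0104, and 0.0748 without TSA replicate 2). Adgrv1, a receptor of the links between stereocilia, rose by 2.22 ± 0.41 (adjusted p = 0.00548). Ush1c, a scaffold protein of the hair bundle, changed by −2.06 ± 0.45 (adjusted p = 0.0121, and 0.135 without TSA replicate 2).

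**Figure D2:**
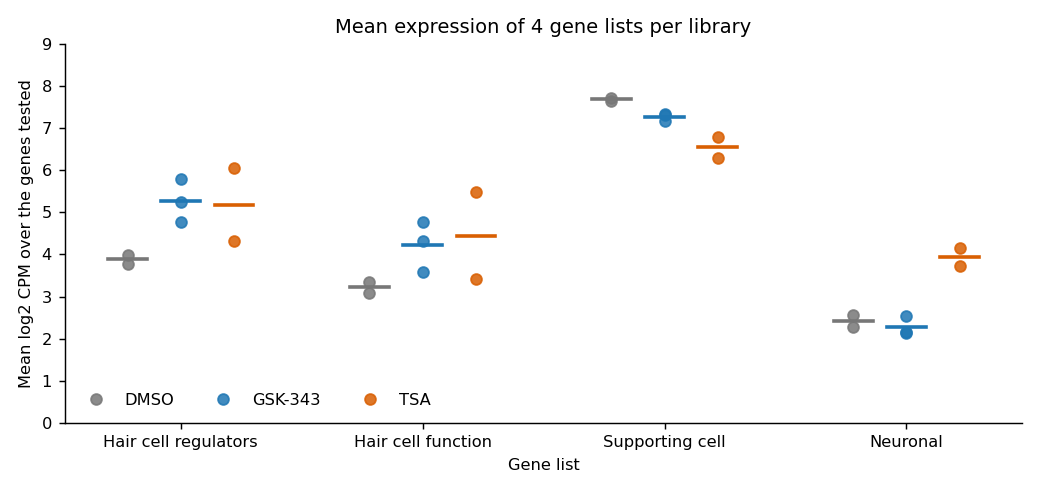
Mean log2 CPM over the tested genes of 4 lists (hair cell regulators, 18 genes; hair cell function, 60; supporting cell, 46; neuronal, 40) in each library, 1 dot per library and a bar at the group mean. The TSA libraries lie at 5.49 and 3.41 for hair cell function, and at 4.16 and 3.72 for the neuronal list, above every DMSO and GSK-343 library there.

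Imprinted genes and genes of antigen presentation went both ways between the compounds. Of 32 imprinted genes tested, 8 rose and 4 fell with TSA relative to GSK-343 (11 and 6 adjusted over the list alone; median 0.15; camera adjusted p = 0.174). Rian and Meg3, long non-coding RNAs of one imprinted cluster, rose by 5.27 ± 0.58 and 3.11 ± 0.46, and the paternally expressed zinc finger gene Peg3 by 1.96 ± 0.34, while the organic cation transporter gene Slc22a3 fell by 2.51 on the log2 scale (SE 0.38). Of 11 genes of MHC class I presentation tested, 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.202). H2-D1, a class I heavy chain, rose by 3.59 ± 0.64, and Tapbp, which loads peptides onto class I molecules, changed by −1.90 ± 0.35 (adjusted p = 0.00567, and 0.0847 without TSA replicate 2). H2-D1 belongs to a family of near-identical genes, so its call is uncertain.

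By the fixed rule, the largest rises with TSA over GSK-343 among well expressed genes were Jakmip2, a protein that binds Janus kinases and microtubules, and Kcnt1, a sodium-activated potassium channel. Neither had a count in any GSK-343 library, and with a floor of 3 counts per library they were at least 38.2-fold and at least 33.9-fold higher with TSA. Dgkk, a diacylglycerol kinase, had 125 counts over the TSA libraries and 1 over the GSK-343 libraries. Next by size came Rpl15-ps3, a pseudogene whose reads may be shared with Rpl15, so its call is uncertain. The largest decreases were those of Tnnt1, the slow skeletal troponin T, with 2 counts with TSA and 181 with GSK-343, of Lrmp, with a log2 fold change of −4.97 ± 0.94, and of Cysltr2, a leukotriene receptor, with −4.86 ± 1.02. The antisense RNA Nr6a1os had 3 counts with TSA and 143 with GSK-343. Car14, a membrane carbonic anhydrase, fell from 233 ± 102 to 8.33 ± 7.22 CPM and Tril, a co-receptor of innate immune signalling, from 490 ± 82.8 to 26.1 ± 23.3 CPM (log2 fold changes −4.79 ± 0.60 and −4.22 ± 0.55). Without TSA replicate 2, Kcnt1, Lrmp, Cysltr2 and Nr6a1os had adjusted p of 0.0926, 0.0748, 0.255 and 0.231. Cysltr2 had 0.104 without TSA replicate 1, Nr6a1os 0.0774 without GSK-343 replicate 1, and Kcnt1 0.0702 by the Wald test of DESeq2. Over all 14907 genes tested, 752 were higher and 846 lower with TSA (10.7%), of which 95 had no count in 1 of the groups. Scaling by total count, which moved the median of all genes to 0.20, gave 1020 higher and 431 lower, a share of 70.3% higher against 47.1%; limma on TPM gave 768 and 187. Without TSA replicate 2 only 83 genes were higher and 79 lower; without TSA replicate 1, 437 and 650; without GSK-343 replicate 2, 422 and 557; and without GSK-343 replicate 3, 378 and 449. Mitochondrial ribosomal RNA held 10.4% and 18.1% of the counts with TSA and 3.47% to 8.60% with GSK-343.

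**Figure D3:**
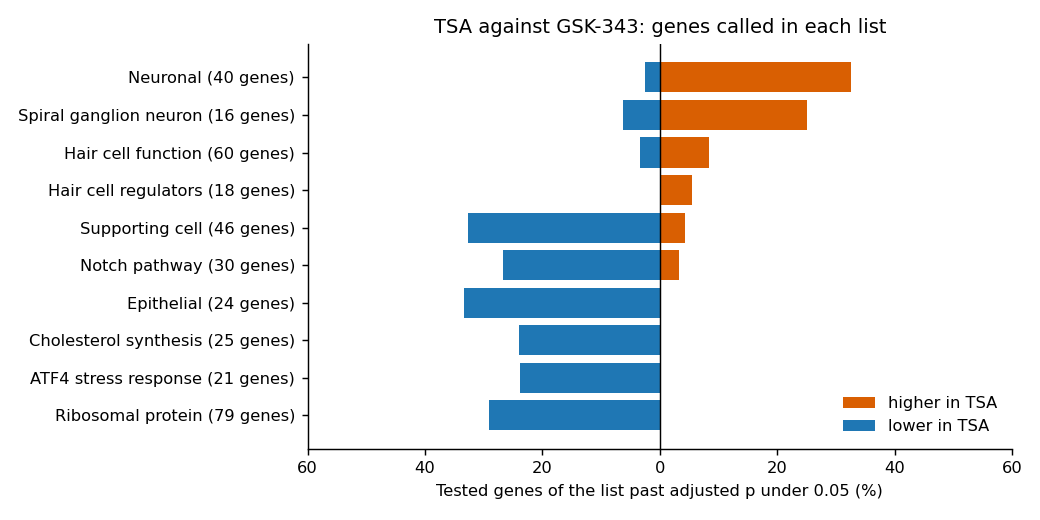
Percentage of the tested genes of 10 lists that passed an adjusted p of 0.05 in TSA against GSK-343, with genes higher in TSA to the right (orange) and lower in TSA to the left (blue). Of 40 neuronal genes 13 were higher, and of 79 ribosomal protein genes 23 were lower.

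The second comparison asks what the deacetylase inhibitor changed relative to the solvent, across the difference in layout described above. Some hair cell genes were higher with TSA than in DMSO. The rise of the function list rested on TSA replicate 1, and the regulator list was not called. Pou4f3, a transcription factor needed for hair cell survival, stood at 259 ± 263 CPM with TSA and 7.72 ± 6.78 CPM in DMSO (log2 fold change 5.08 ± 1.06, adjusted p = 0.00752). Gfi1, another hair cell transcription factor, rose by 5.06 ± 1.09 and Atoh1, the factor that starts hair cell differentiation, by 2.28 ± 0.60 (adjusted p = 0.0119). Calb2, a calcium buffer of inner hair cells that is also in the spiral ganglion list, rose by 5.78 ± 0.85, Gpsm2 by 2.49 ± 0.37 and the synaptic vesicle adaptor gene Snap91 by 2.34 ± 0.50, whereas Triobp, which forms the rootlets of stereocilia, fell by 2.55 on the log2 scale (SE 0.52). Of 60 hair cell function genes tested, 16 rose and 3 fell, or 19 and 3 adjusted over the list alone (median 1.56; camera adjusted p = 0.00484; adjusted p = 0.987 with an estimated correlation). Of 18 hair cell regulators, 9 rose and 2 fell, also adjusted over the list alone (median 1.61; camera adjusted p = 0.24). Several calls depended on the libraries and scaling used. Without TSA replicate 1 the function list had a median of −0.10, where the median of all genes was −0.38. It had an adjusted p of 0.0766 without DMSO replicate 2 and 0.0674 with total count scaling. The regulator list had an adjusted p of 0.987 by camera with an estimated correlation and 0.431 by fry. Its mean log2 CPM was 6.06 and 4.31 in the TSA libraries, and 3.98 and 3.77 in DMSO. Atoh1 had a log2 fold change of 1.10 (adjusted p = 0.29) and Gfi1 one of 3.08 (adjusted p = 0.0704) without TSA replicate 1. Without DMSO replicate 1, Atoh1 and Pou4f3 had adjusted p of 0.0651 and 0.0769, and Pou4f3 had 0.0573 without GSK-343 replicate 1.

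Supporting cell genes were lower with TSA than in DMSO. Of 46 tested, 26 fell and 3 rose, or 29 and 3 adjusted over the list alone, with a median of −1.06 (camera adjusted p = 6.67e-05; adjusted p = 0.666 with an estimated correlation). Cdkn1b, the cell cycle inhibitor p27 that keeps these cells out of division, stood at 53.2 ± 8.39 CPM with TSA and 658 ± 110 CPM in DMSO (log2 fold change −3.63 ± 0.43, adjusted p = 5.97e-05). Fabp7, a fatty acid binding protein of glia-like cells, changed by −5.02 ± 0.54, Otogl, a protein of the tectorial membrane, by −3.87 ± 0.39 and Emid1 by −3.52 ± 0.47. Among Notch pathway genes, 4 rose and 6 fell of 30, also adjusted over the list alone (median −0.34, but mean 0.08, and a median of 0.40 with total count scaling; camera direction down, adjusted p = 0.475). The ligand gene Jag1 fell from 1279 ± 382 to 351 ± 56.7 CPM (log2 fold change −1.86 ± 0.35), Hey1 by 2.47 on the log2 scale (SE 0.35) and the receptor gene Notch3 by 1.91 (SE 0.37).

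Neuronal genes were higher with TSA than in DMSO too: 14 rose and 0 fell of 40, also adjusted over the list alone (median 1.30; camera adjusted p = 0.00119; adjusted p = 0.658 with an estimated correlation). Scg5 rose from 1.21 ± 0.128 to 154 ± 26.7 CPM (log2 fold change 6.96 ± 0.53, adjusted p = 2.42e-06), Nefl by 6.63 ± 1.03, Snap25 by 4.88 ± 0.68 and Stmn2 by 2.92 ± 0.46. Of 11 MHC class I presentation genes, 5 rose and 0 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.658 with an estimated correlation). Tap1, a peptide transporter for antigen presentation, had no count in DMSO and was at least 20.3-fold higher with TSA. Of 12 histone acetylation genes, 0 rose and 7 fell, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.658 with an estimated correlation). The acetyltransferase genes Crebbp, Kat6a and Kat6b changed by −2.99 ± 0.38, −2.61 ± 0.38 and −1.92 ± 0.41. Of 11 histone deacetylase genes, 1 rose and 2 fell, or 2 and 3 adjusted over the list alone (median 0.43, but mean −0.12; camera direction up, adjusted p = 0.949): Hdac3 changed by 1.37 ± 0.34 and Hdac2 by −1.37 ± 0.36. They had adjusted p of 0.0646 and 0.0521 without DMSO replicate 1. Hdac2 had 0.0591 without DMSO replicate 2, and 0.117 and 0.0603 without TSA replicate 1 and 2. With total count scaling it changed by −0.67 (adjusted p = 0.15). The MHC list had adjusted p of 0.138 and 0.146 without DMSO replicate 1 and 2 and 0.0674 with total count scaling. The acetylation list had 0.0513, 0.147 and 0.065 without DMSO replicate 1, DMSO replicate 2 and TSA replicate 1 and 0.0674 with total count scaling.

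Transcripts of the mitochondrial genome, which differ with the make-up of the libraries described above, were lower in TSA for 28 of 30 tested, also adjusted over the list alone, with 0 higher (median −7.38, or −3.91 with genes at 0 set to their bounds; camera adjusted p = 2.82e-17; adjusted p = 0.666 with an estimated correlation). With the GC and length trend removed, 11 of the 30 were called lower (camera adjusted p = 7.23e-04). The median length of these transcripts was 139.5 bases. The 184 shortest tested genes of known length had a median log2 fold change of −5.23 for TSA and −4.52 for GSK-343 against DMSO. Between TSA and GSK-343, which share a layout, it was −0.07. Decreases of such short transcripts against DMSO therefore cannot be told apart from the difference in layout. The ribosomal RNA mt-Rnr1 stood at 108223 ± 5037 CPM in DMSO and 666 ± 98.8 CPM with TSA. Ribosomal protein genes went both ways, with 18 higher and 20 lower of 79 (21 and 20 adjusted over the list alone; median −0.03 and mean −0.10, but a median of 0.66 with total count scaling; camera direction up, adjusted p = 0.95). By the fixed rule the largest rises were those of Rn7sk, a small nuclear RNA that restrains transcription elongation, and Dtx1, neither of which had a count in DMSO, at least 46.3-fold and at least 32.3-fold higher. Adam11, a catalytically inactive member of a membrane protease family, was at least 30.6-fold higher. The largest decreases were those of the microRNA locus Mir6236, at least 576-fold lower, and the mucin genes Muc4 and Muc16, at least 193-fold and at least 93.3-fold lower. Mir6236, at 123 bases, is one of the short transcripts. By the Wald test of DESeq2, Muc16 had an adjusted p of 0.0884. Over all genes, 1957 were higher and 2402 lower with TSA (29.2% of 14907), of which 512 had no count in 1 of the groups. Scaling by total count moved the median of all genes from −0.05 to 0.65 and gave 3871 higher and 1307 lower, 74.8% higher against 44.9%; limma on TPM gave 5100 and 2468. Leaving out 1 library gave 1069 higher and 1335 lower without DMSO replicate 1, 1261 and 1633 without DMSO replicate 2, 1291 and 1284 without TSA replicate 1, and 1068 and 916 without TSA replicate 2.

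The third comparison asks what the EZH2 inhibitor changed relative to the solvent, across the same difference in layout. Transcripts for ribosomal proteins, epithelial junctions, sterol synthesis and the ATF4 response included many that rose, and for the last 3 groups fewer did so once the GC and length trend was removed. Of 79 ribosomal protein genes, 41 rose and 11 fell, or 44 and 14 adjusted over the list alone (median 1.06; camera adjusted p = 2.59e-04; adjusted p = 0.87 with an estimated correlation). Rplp1 rose from 61.5 ± 3.26 to 659 ± 79.3 CPM (log2 fold change 3.42 ± 0.33), and Rpl27 by 6.39 ± 0.44, while Rpl39 fell by 4.23 on the log2 scale (SE 0.45); ribosomal protein genes have many pseudogene copies, so single calls are uncertain. Of 24 epithelial genes, 10 rose and 2 fell, or 14 and 4 adjusted over the list alone (median 0.99; camera adjusted p = 0.063). Cldn7 stood at 586 ± 156 CPM against 16.8 ± 4.32 CPM (log2 fold change 5.13 ± 0.41, adjusted p = 1.12e-06), and Spint1, an inhibitor of membrane proteases, rose by 2.30 ± 0.35, whereas Cldn6 fell by 1.65 (SE 0.33). Of 25 cholesterol synthesis genes, 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.146), with Srebf2 at 2.05 ± 0.35 and Tm7sf2, a sterol reductase, at 3.14 ± 0.47. Of 21 ATF4 response genes, 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.146). Shmt2 rose by 1.93 ± 0.38, but by 0.84 with the GC and length trend removed (adjusted p = 0.105), and Nupr1, a stress-induced regulator, fell by 2.68 (SE 0.60). Log2 fold changes followed GC content in this comparison (Spearman 0.347 over 14870 genes, which are not independent replicates). With that trend removed, 6 epithelial genes rose and 5 fell (median 0.20; camera adjusted p = 0.666), 6 cholesterol genes rose and 1 fell (0.455), and 2 ATF4 genes rose and 2 fell (0.605), while 40 ribosomal protein genes rose and 16 fell (0.00249). With an estimated correlation, no list in this comparison had a camera adjusted p under 0.87. Leaving out TSA replicate 1 or 2, which are in neither group, let more genes pass the filter (17764 and 17902 tested, against 14907). The median of all genes then went from −0.04 to −0.31. Lists that passed without a TSA library were thus ranked against another background of genes. Without GSK-343 replicate 1 the epithelial list had an adjusted p of 0.0352. Without TSA replicate 1 it had 0.00592, the cholesterol list 0.0252 and the ATF4 list 0.0194. Both other lists were also past the threshold without TSA replicate 2 (0.0247 and 0.0236), the cholesterol list without DMSO replicate 1 or GSK-343 replicate 2 (0.0389 and 0.0441). The epithelial list was so without TSA replicate 2, DMSO replicate 1 or DMSO replicate 2 (0.00428, 0.0177 and 0.0303).

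Hair cell regulators were higher with GSK-343 than in DMSO for 8 of 18 genes and lower for 2, also adjusted over the list alone (median 1.55; camera adjusted p = 0.146). Of 60 hair cell function genes 14 rose and 4 fell, also adjusted over the list alone (median 0.92; camera adjusted p = 0.063, and 0.0347 with the GC and length trend removed). Pou4f3 stood at 195 ± 114 CPM with GSK-343 and 7.72 ± 6.78 CPM in DMSO (log2 fold change 4.67 ± 1.02, adjusted p = 0.00572). Atoh1 rose by 2.66 ± 0.58 (adjusted p = 0.00252), Barhl1, a homeobox factor of hair cells, by 4.95 ± 1.01, Calb2 by 4.42 ± 0.80 and Ctbp2, which makes the synaptic ribbon, by 2.32 ± 0.52. Rfx3, a factor of ciliogenesis, fell by 2.49 (SE 0.35) and had −0.60 with an adjusted p of 0.192 when the GC and length trend was removed. Of 46 supporting cell genes, 7 rose and 13 fell, or 8 and 14 adjusted over the list alone (median −0.35, and 0.12 with total count scaling; camera adjusted p = 0.429). Otogl changed by −3.79 ± 0.33, Cdkn1b by −3.45 ± 0.37 and S100a1 by 3.48 ± 0.41. Without DMSO replicate 1, Pou4f3 had an adjusted p of 0.0632 and the function list 0.0349; without GSK-343 replicate 1, Pou4f3 had 0.0629. The function list had a camera adjusted p of 0.00331 without GSK-343 replicate 2, but 0.143 and 0.226 without GSK-343 replicate 1 and 3. The regulator list had 0.0441, 0.171 and 0.246 in the same order. With an estimated correlation both lists had 0.87. By fry the function list had 0.424 and the regulator list 0.322.

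Of 76 listed transcription factor genes that Polycomb complexes are known to repress in other cells, 11 had enough counts to be tested, so the list says little about genes that are silent here. Of these 11 transcription factor genes tested, 2 rose and 6 fell, or 2 and 7 adjusted over the list alone (median −1.17; camera adjusted p = 0.53). Isl2, a factor of neuronal identity, rose by 2.16 ± 0.44, but by 1.09 with the GC and length trend removed (adjusted p = 0.0504), while Ebf3 and Prdm12, other neuronal factors, changed by −1.33 ± 0.33 and −2.28 ± 0.58 (adjusted p = 0.0716 and 0.0794 without DMSO replicate 1). Of 13 genes of Polycomb repressive complex 2 and its demethylases, 2 rose and 3 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.649), with Rbbp7, a histone-binding subunit, at 1.44 ± 0.34. The HOX list had 0 genes with enough counts to be tested. Of 40 neuronal genes, 8 rose and 10 fell, also adjusted over the list alone (median −0.21, and 0.24 with total count scaling; camera adjusted p = 0.959). Scg5 and Uchl1, a ubiquitin hydrolase, rose by 4.78 ± 0.50 and 2.49 ± 0.38, and Stmn2 changed by −2.53 ± 0.44. Of 32 imprinted genes, 4 rose and 12 fell, or 6 and 12 adjusted over the list alone (median −0.11, and 0.36 with total count scaling; camera adjusted p = 0.699), with Peg3 at −2.28 ± 0.34 and its neighbour Usp29 at −4.74 ± 0.84. Of 30 transcripts of the mitochondrial genome, 29 were lower, also adjusted over the list alone (camera adjusted p = 1.35e-18; adjusted p = 0.87 with an estimated correlation), and 11 with the GC and length trend removed (camera adjusted p = 2.58e-04). Here too, decreases of short transcripts cannot be told apart from the difference in layout.

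The largest rises with GSK-343 by the fixed rule were those of Rn7sk, Hsd3b7, a bile acid synthesis enzyme, and Dhrs13, a short-chain dehydrogenase, none of which had a count in DMSO; they were at least 245-fold, at least 62.9-fold and at least 40.6-fold higher. The largest decreases were those of the short transcript Mir6236, at least 654-fold lower, the pseudogene Rpl15-ps3, at least 316-fold lower, and Muc16, at least 106-fold lower. Over all genes, 2695 were higher and 3208 lower (39.6% of 14907), of which 567 had no count in 1 of the groups. Scaling by total count moved the median of all genes from −0.04 to 0.42 and gave 3948 higher and 2273 lower, 63.5% higher against 45.7%; limma on TPM gave 4219 and 3163.

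Changes relative to DMSO were compared between the compounds. Both were higher than DMSO for 1385 genes and lower for 1760, and 24 genes were called in opposite directions. Lists of these sizes drawn independently would share 354 and 517 genes, with 855 in opposite directions. In 20 simulations of all 7 libraries without a change between groups, where the comparisons share the DMSO libraries as here, at most 1 gene was called in both. No gene differed there, so this does not show what sharing controls gives when many genes differ. Log2 fold changes correlated at 0.802 across 14907 genes (simulated median 0.541), with a covariance of 4.71 against a simulated 0.382. The controls were not split, since each part would hold 1 DMSO library. Part of the excess may therefore come from the shared controls, and the shared layout difference may add to it. The genes higher with both compounds included 7 of 18 hair cell regulators (Atoh1, Barhl1, Gfi1 and Pou4f3 among them) and 12 of 60 hair cell function genes. Those lower with both included 10 of 46 supporting cell genes (Cdkn1b, Fabp7, Jag1 and Otogl among them) and 28 of 30 mitochondrial transcripts. With TSA, 225 genes were higher than in both other groups, 8 of them from the neuronal list, and 297 were lower than in both, including 10 supporting cell genes. With GSK-343, 444 were higher than in both other groups, including 15 ribosomal protein and 7 epithelial genes, and 385 lower, including 8 neuronal and 6 imprinted genes. In the simulations each of these 4 counts was at most 1, which the lack of any change there set in advance. Without 1 library the number of genes moved the same way by both compounds ranged from 1671 to 3567 around 3145; it was 1744 without DMSO replicate 1, 1837 without TSA replicate 1 and 1671 without TSA replicate 2.

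Genes fixed in advance follow, with the values of each library for Atoh1, Pou4f3, Gfi1, Myo7a and Sox2. Cdkn1b was given above. Atoh1 (chromosome 6, 64729125 to 64731245 of mm10) stood at 5.62 and 6.26 CPM in DMSO, 35.1, 38.7 and 39.3 CPM with GSK-343, and 45.4 and 12.3 CPM with TSA; TSA and GSK-343 did not differ past the threshold (log2 fold change −0.39 ± 0.51, adjusted p = 0.669). Pou4f3 (chromosome 18, 42394539 to 42397249) stood at 2.92 and 12.5, 212, 73.5 and 299, and 445 and 73.3 CPM in the same order. Gfi1 stood at 2.70 and 0.26, 16.1, 4.87 and 15.5, and 91.0 and 12.6 CPM. Its rise with GSK-343 over DMSO was 2.97 ± 1.00 (adjusted p = 0.0311, and 0.184, 0.0692 and 0.0653 without DMSO replicate 2, GSK-343 replicate 1 and GSK-343 replicate 3), and 1.95 with the GC and length trend removed (adjusted p = 0.144). Myo7a, the unconventional myosin of hair bundles, stood at 17.3 and 3.91, 40.8, 10.2 and 50.2, and 146 and 21.4 CPM, and its log2 fold change of 2.97 ± 1.01 in TSA over DMSO had an adjusted p of 0.0501. Sox2, a transcription factor of supporting cells (chromosome 3, 34650405 to 34652461), stood at 188 and 181, 146, 165 and 149, and 100.3 and 92.1 CPM. Its difference of −0.94 ± 0.33 between TSA and DMSO (adjusted p = 0.0404) was −0.23 with total count scaling (adjusted p = 0.609) and missed the threshold without any 1 of DMSO replicate 1 or 2, GSK-343 replicate 2 or 3 and TSA replicate 1 or 2 (adjusted p = 0.154, 0.12, 0.054, 0.0667, 0.166 and 0.243). Hes5 was higher with GSK-343 than in DMSO by 0.99 ± 0.30 (adjusted p = 0.0163), but by 0.23 with the GC and length trend removed (adjusted p = 0.6). The call was lost without DMSO replicate 1 or 2 or GSK-343 replicate 2 (adjusted p = 0.0595, 0.131 and 0.0539). The cell cycle inhibitor gene Cdkn1a stood at 34.7 ± 0.322 CPM with TSA, 84.6 ± 39.9 CPM with GSK-343 and 232 ± 6.28 CPM in DMSO (log2 fold changes against DMSO −2.74 ± 0.46 and −1.45 ± 0.39, adjusted p = 7.97e-04 and 0.00798). With total count scaling the change with GSK-343 was −0.99 (adjusted p = 0.0578). Cdkn2a, another such inhibitor, had 2 counts in TSA replicate 2 and 0 in the other libraries and was not tested. Ezh2, the target of GSK-343, did not pass the test there (log2 fold change −0.97 ± 0.42, adjusted p = 0.0773), nor did the deacetylase gene Hdac1 with TSA (0.43 ± 0.43, adjusted p = 0.472).

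**Figure D4:**
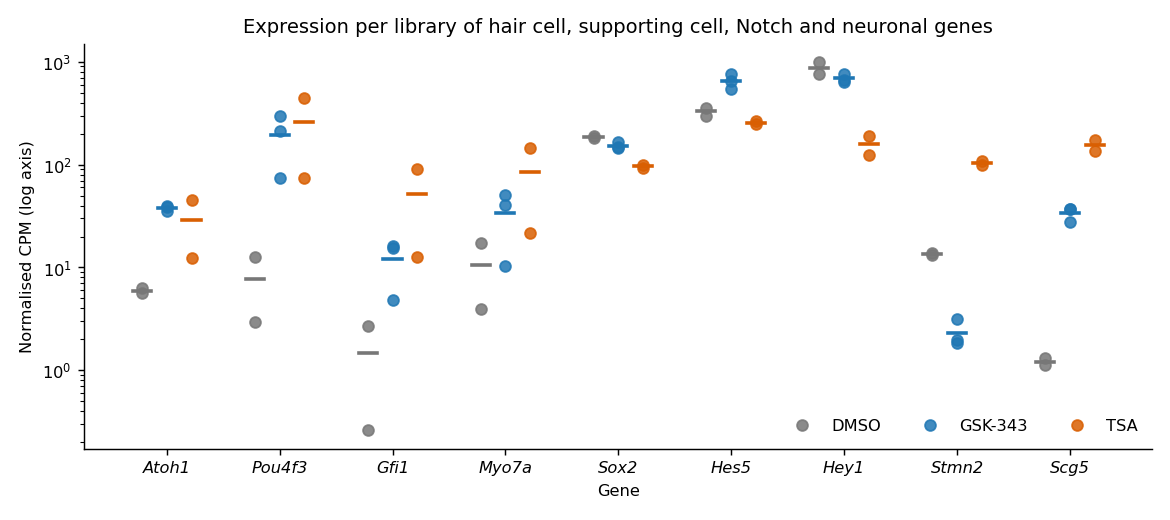
Normalised CPM (log axis) of 9 genes in each library, 1 dot per library and a bar at the group mean, for DMSO (grey), GSK-343 (blue) and TSA (orange). Pou4f3 ranges from 73.3 to 445 CPM between the TSA libraries, whereas Stmn2 lies at 108 and 98.8 CPM there and at most at 3.16 CPM with GSK-343.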

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

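The GC and length correction and the restriction to protein-coding nuclear genes were chosen only after the results were seen. Where no reason is given for a change, the cause was not tested.

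Total count scaling, which drops the composition factors that differ between DMSO and the treated libraries, gave 3871 genes higher and 1307 lower for TSA against DMSO (1957 and 2402 with TMM), and 431 lower for TSA against GSK-343 (846 with TMM). Limma on TPM, which tests other genes in another unit, gave 5100 and 4219 higher for TSA and GSK-343 against DMSO, and 187 lower for TSA against GSK-343. An adjusted p under 0.01 left 897 higher and 1123 lower, 1557 and 2107, and 134 and 183 in TSA against DMSO, GSK-343 against DMSO and TSA against GSK-343. Leaving out 1 library gave 1068 to 2350 higher and 916 to 2874 lower for TSA against DMSO, the lowest without TSA replicate 2 and the highest without GSK-343 replicate 1, and 83 to 940 higher and 79 to 1171 lower for TSA against GSK-343, with the same libraries at the ends. Genes moved the same way by both compounds numbered 1671 to 3567 around 3145.

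With the replicate number as a block (replicate block), TSA against GSK-343 had 325 genes higher and 527 lower, and the overlap of calls was 2534. In that comparison the calls of the cholesterol, ATF4, medial, Notch pathway, Notch effector and spiral ganglion lists (adjusted p = 0.053 each), the fatty acid list (0.21) and Dtx1 (0.0682) were lost. Against DMSO, those of Pou4f3 (0.0907 with TSA and 0.11 with GSK-343), Rn7sk (0.104 and 0.0617) and Sox2 with TSA (0.0818) were lost. Residuals of samples with the same number correlated at −0.143 to 0.0394 over 9811 genes. They were centred within each group, so the 2 libraries of a group of 2 mirror each other. GSK-343 replicate 1 had −0.143 with TSA replicate 1 and 0.143 with TSA replicate 2. These values therefore cannot tell whether samples with the same number share a culture.

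Lists were tested with limma camera at the preset correlation unless another test or correlation is named. A fit without 1 DMSO or TSA library leaves 1 library in that group. Its p-values do not measure the spread between samples of that group. For TSA against DMSO, the hair cell regulator list had an adjusted p of 0.00539 without a low-count filter and of 1.38e-04 (without TSA replicate 2) to 0.47 (without TSA replicate 1) with 1 library left out, against 0.24. The hair cell function list had 0.987 with an estimated correlation, 0.401 by fry, 0.0674 with total count scaling, and 1.07e-11 (without TSA replicate 2) to 0.358 (without TSA replicate 1), against 0.00484. The supporting cell list had 0.666 with an estimated correlation, against 6.67e-05. For GSK-343 against DMSO, the regulator list had 7.69e-04 without a low-count filter and 0.014 (without TSA replicate 2) to 0.246 (without GSK-343 replicate 3), against 0.146. The function list had 1.82e-06 without the filter, 0.0347 with the GC and length correction, and 0.00194 (without TSA replicate 1) to 0.226 (without GSK-343 replicate 3), against 0.063. The supporting cell list ranked higher than other genes without the filter (0.395), although its median stayed below 0 (−0.25, with 8 genes higher and 15 lower), since the median of all genes was −2.11 there. For TSA against GSK-343, the regulator list turned from lower to higher with the replicate block (0.724), the GC and length correction (0.907), and without TSA replicate 2 (0.0503) or GSK-343 replicate 3 (0.673), and ranged from 0.0106 (without TSA replicate 1) to 0.846 (without GSK-343 replicate 1). The function list turned from higher to lower without GSK-343 replicate 2 (0.965) and without TSA replicate 1 (0.00991), and was higher at 1.02e-07 without TSA replicate 2, and the supporting cell list had 0.458 with an estimated correlation.

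Log2 fold changes that changed sign were those of Adgrv1 (0.0589) and Mtf2 (0.028) in GSK-343 against DMSO and Atoh1 (0.0406) in TSA against GSK-343 with the GC and length correction, and those of Sox2 (0.20) and Hdac1 (0.34) in GSK-343 against DMSO, Hes5 (0.34) in TSA against DMSO and Cdkn1b (0.0613) in TSA against GSK-343 with total count scaling. With 1 library left out, TSA against GSK-343 ranged from −1.62 to 0.25 for Atoh1, −1.41 to 1.17 for Pou4f3, −0.66 to 2.10 for Myo7a and −0.44 to 0.0294 for Cdkn1b; Ezh2 ranged from −0.0672 to 0.72 in TSA against DMSO and Hdac1 from −0.44 to 0.19 in GSK-343 against DMSO.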

Other observations

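Other gene groups tested with limma camera help to place these changes. Cell cycle genes of the S phase rose for 3 and fell for 0 of 24 tested in TSA against GSK-343 (the same adjusted over the list alone; median 0.44; adjusted p = 0.222), and for G2 and M phase genes 0 of 12 were called (0 adjusted over the list alone; median 1.79; adjusted p = 0.0508). The mean log2 CPM of the G2 and M phase genes was 1.42 and 2.95 in the TSA libraries and 0.86 to 1.42 with GSK-343. That list had adjusted p of 0.0086 without a low-count filter, 0.00101 without TSA replicate 1 (3 genes higher) and 0.0457 without GSK-343 replicate 1, so its shift rests mainly on TSA replicate 2. Interferon response genes rose for 3 and fell for 0 of 13, also adjusted over the list alone (median 0.90; adjusted p = 0.0508), and Schwann and glial genes rose for 0 and fell for 3 of 10 (0 and 4 adjusted over the list alone; median −0.87; adjusted p = 0.0508). The interferon list had adjusted p of 0.00495, 0.0478 and 0.0388 without TSA replicate 2, GSK-343 replicate 2 and GSK-343 replicate 3, 0.0353 with the GC and length correction, 0.0278 with protein-coding nuclear genes only and 4.61e-04 without a low-count filter. The Schwann and glial list had 0.0457 and 0.0215 without GSK-343 replicate 1 and 2, 0.0484 with DESeq2's size factors, 0.0399 with total count scaling and 0.0391 without a low-count filter. With an estimated correlation the G2 and M phase, interferon and Schwann and glial lists had adjusted p of 0.621, 0.458 and 0.505. In GSK-343 against DMSO, 10 of 25 genes of lysosomes and autophagy rose and 3 fell (10 and 4 adjusted over the list alone; median 0.46; adjusted p = 0.15). Mest, an imprinted gene, rose in TSA against DMSO by 2.24 ± 0.40 on the log2 scale (edgeR adjusted p = 0.00123), and Six2, a homeobox factor, changed by −4.26 ± 0.68 (adjusted p = 7.9e-04).

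Many genes differed between DMSO and each treated group, with 4359 called for TSA and 5903 for GSK-343. All 3 tests of this pattern were chosen only after it was seen. For TSA against DMSO, GC content and transcript length as the whole cause are argued against, since 4478 genes were called after the GC and length correction. Of the 1957 genes higher and 2402 lower before it, 1638 and 2029 stayed. For GSK-343 against DMSO the trend on GC content was stronger (Spearman 0.347 against 0.126). There 1785 of 2695 higher and 2223 of 3208 lower genes stayed. Pseudogenes were called lower in TSA against DMSO 3.63 times as often as protein-coding genes (49.7% against 13.7%) but 0.548 times as often in TSA against GSK-343, where the layout is shared, so the layout of the DMSO libraries may account for that part. For the other genes, the layout and library batch cannot be told apart from the treatments, because 0 libraries have a layout other than that of their side of the comparison.

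The hair cell function list was higher in TSA than in DMSO, although its median was −0.10 without TSA replicate 1. In that fit the median of all genes was −0.38, against −0.05 with all libraries. The tests below were chosen before this pattern was seen, except the GC and length correction itself, added after the data were seen. With that correction the function list kept its direction (median 1.63 against 1.56, camera adjusted p = 0.00139 with the preset correlation). This argues against GC content and length as the whole cause. With an estimated correlation the uncorrected list had 0.987, so the rise of the list as a whole is uncertain. Of 57 function genes with at least 20 counts in TSA, 55 were higher in the same TSA library (96.5%; these genes are not independent, with an estimated correlation of 0.503), so a varying number of hair cells among the sorted cells may contribute, although the GFP sort should have removed them. A conversion of supporting cells in 1 culture more than in the other could give the same shared movement. Since the DMSO layout is also confounded here, neither reading is settled.

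Neuronal genes were higher in TSA than in GSK-343, and the tests below were chosen before it was seen, except the GC and length correction, which was added after the data were seen. The list kept its direction with that correction (adjusted p = 3.27e-10) and without either TSA library (largest adjusted p = 2.34e-05), which argues against GC content and length or 1 TSA library as the whole cause. These adjusted p-values used camera's preset correlation, and the uncorrected list had 0.28 with an estimated one. Spiral ganglion neurons that escaped the GFP sort could bring neuronal transcripts. The median of 5 of the 6 abundant neuron transcripts chosen was 2.21 (SD 2.11). Nefl was at 2.38 and Snap25 at 2.89, but Uchl1 at −2.12 and Tubb3, with 6 and 13 counts in the TSA libraries, at −0.09. The 13 neuronal genes called higher had a median of 3.73, but they were picked for rising. The 5 transcripts are in the same list, so this test could hardly favour neurons. Neurons and a response of the supporting cells cannot be told apart. The sixth, Prph, was not tested, with 2 and 6 counts in the TSA libraries and 0 elsewhere; of the 40 neuronal genes, 28 had counts in all DMSO and GSK-343 libraries, and 4 are also in the spiral ganglion list. Derepression by deacetylase inhibition may also explain the rise, but this was not tested.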
